A study of Mus musculus with 59 samples.

How the data were processed

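The series held 59 samples of mouse uterus from C57/B6 animals of 4 ages. Chromatin immunoprecipitation with sequencing was done on native (uncrosslinked) chromatin from few nuclei. Antibodies against H3K4me3, a histone mark of promoters, and H3K27ac, a histone mark of active promoters and enhancers, each gave 27 libraries from the same 27 animals, and 5 input libraries were not used here. Aliquots of 20000 nuclei were digested with micrococcal nuclease for 7.5 minutes and incubated with 250 ng of antibody, and paired reads of 75 bases were sequenced, per the labels' protocols.

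Both deposited tables held log2 RPKM, the log2 of reads scaled for peak length and for library total, with a row per peak and a column per library, as the authors named them. Reads were aligned to GRCm38 with Bowtie2, per the submitters' processing notes. MACS2 2.2.9.1, DiffBind 3.8.0, DESeq2, ChIPseeker 1.34.1 and deepTools 3.5.1 were also named, without the order or role of each, per the submitters' processing notes. No step beyond the RPKM scaling was stated for the tables, and none of the authors' own test results was used here.

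The values were checked before use. Each value gave a whole read, within 0.05, or the value that the tables held for a peak without reads, which equalled 0.9 reads, in 100.0% of values of both marks. That arithmetic gave total reads of 6.835 M to 48.29 M per H3K4me3 library and 7.604 M to 16.945 M per H3K27ac library, with medians of 120 and 50 reads per peak. Libraries of a group differed by more than counting error alone would give. The lowest chi-square per degree of freedom between any 2 libraries of a group was 1.98 over 174 pairs, and 0 pairs held identical values. Each animal had a single library per mark, so the excess holds differences in library preparation as well as between animals.

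Peaks on chromosomes 1 to 19 and X were tested, 25827 of 25835 for H3K4me3 and 54354 of 54362 for H3K27ac; the 8 peaks of each mark on chromosome Y were left out because they held 0 or 1 reads per library. Gene names were those of the tables, which gave a gene to peaks within 5 kb. Of 18819 gene symbols in the tables, 16719 were found in the RefSeq gene table of GRCm38.p6, from which gene extents were taken. Strand came from the deposited tables and set which end of the extent was the gene start. Peaks of the 2100 other symbols had no gene start and were counted away from promoters. A peak within 1 kb of its gene's start was called a promoter peak. Only a single RefSeq start of the named gene was used. Peaks at its other starts, or at starts of other genes, were thus counted away from promoters. Exons, introns and base composition were not examined, since the RefSeq gene table holds gene extents alone.

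Values were quantile normalized across the 27 libraries of a mark and fitted with limma 3.58.1 (lmFit, eBayes with the mean-variance trend) in a single model of 4 group means, two-sided, with Benjamini-Hochberg adjustment over all tested peaks and a threshold of 0.05. Contrasts were aged groups 1, 2 and 3 against young, aged group 2 against aged group 1, and aged group 3 against aged group 2, with a linear term in weeks of age in a further fit. Fold changes are log2 differences of group means, with the standard error (SE) of the model. Libraries carry a code opening with a digit and a mouse number, whose meaning is not stated, and the main model had no covariate.

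Gene lists were tested for aged group 3 against young with limma's camera at a preset inter-gene correlation of 0.01, beside camera with the correlation estimated from the data and limma's fry. Each gene entered with a single promoter peak, that of the highest mean, which left 11718 genes for H3K4me3 and 10714 for H3K27ac. The 31 lists held 699 genes. The 20 pathway lists were oestrogen response, progesterone response, decidualisation and implantation, collagens and matrix, matrix degradation, TGF-beta signalling, inflammatory and senescence-associated secretion, senescence and cell-cycle arrest, proliferation, interferon response, antigen presentation, complement, Wnt signalling, HOX clusters, immediate early genes, circadian clock, heat shock and protein folding, oxidative stress, chromatin regulators, and control genes used in every cell type. The 11 cell type lists were luminal and glandular epithelium, endometrial stroma, smooth muscle, blood endothelium, lymphatic endothelium, pericytes, macrophages and monocytes, T and NK cells, B and plasma cells, all leukocytes, and adipocytes and mesothelium. Lists with under 5 measured genes were not tested. A list score is the mean normalized log2 RPKM of a list's measured genes in a library.

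Genes were named by a rule. For aged group 3 against young, the 12 peaks with the smallest p in each direction were taken among those past the threshold, with a gene symbol other than a predicted or clone name and a higher group mean at or above the lower quartile of peaks, with a single peak per gene. For other contrasts and the age trend 4 per direction were taken, or, where none passed, 3 per direction as values that did not pass. For each list, up to 4 members past the threshold with the smallest p were taken, or else the 2 with the highest mean. The lists, contrasts, tests, naming rule and the first set of alternatives were fixed before the data were examined.

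Library levels (the median deposited log2 RPKM over tested peaks) and scores were compared by exact two-sided permutation tests. The spread between animals of a group was the mean root-mean-square difference between pairs of libraries, tested by permuting group-centred libraries. H3K4me3 peaks were matched to the H3K27ac peak they overlapped most. Simulated data with known changes at few peaks had noise drawn independently for each peak, so they lack variation shared across peaks. On them the aged group 3 against young fit recovered 69% of 100 H3K4me3 peaks changed by 1 on the log2 scale. It recovered 95% of 100 changed by 2, with 10 unchanged peaks called. For H3K27ac in the same comparison it recovered 48% and 97%, with 9 unchanged peaks called.

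That first set was the deposited values without further scaling, median centring, log2(RPKM + 1), leaving out the lowest 25% of peaks, no mean-variance trend, array weights, a threshold of 0.01, the code digit or the mouse number series as a factor, mouse numbers under 100 alone, a replicate block, other peak choices, and leaving out each library. Chosen after seeing the data were voom on the recovered reads, the epithelium minus stroma score or the percent of reads in peaks as a covariate, leaving out code digit 6, fitting only the groups compared, the trend without young libraries, mouse numbers under 100 for the library level, any RefSeq gene start within 1 kb for the lists, and the overlap of calls with split young libraries. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.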

Results

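H3K4me3 and H3K27ac were measured in uterine tissue pieces of young mice aged 9 to 11 weeks (n = 7) and of 3 older groups: aged group 1, 28 to 36 weeks (n = 4), aged group 2, 42 to 48 weeks (n = 6), and aged group 3, 54 to 65 weeks (n = 10). Both marks came from the same animals. Total reads ran from 6.835 M to 48.29 M per H3K4me3 library (median 10.022 M) and from 7.604 M to 16.945 M per H3K27ac library (median 11.162 M). Reads in peaks made up 36.3% to 75.8% of H3K4me3 libraries and 32.3% to 48.7% of H3K27ac libraries. All peak positions are on GRCm38, values are quantile-normalized log2 RPKM, and fold changes are on the log2 scale ± SE.

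The comparison of aged group 3 with young asks how both marks change over the reproductive lifespan of the uterus. In the mean of aged group 3, H3K4me3 was higher at genes of the uterine epithelium and at oestrogen-responsive and interferon-responsive genes. It was lower at genes of the stroma, smooth muscle and extracellular matrix. These lists did not pass with an estimated correlation (smallest adjusted p = 0.436). Not all aged group 3 libraries shared the changes: the oestrogen scores of replicates 3 and 10 (2.46 and 2.11) were not above the young range. The gland transcription factor Foxa2 rose by 1.98 ± 0.33 (from 0.88 to 2.86; adjusted p = 0.000197), and the secreted iron-binding protein gene Ltf rose by 3.95 ± 0.83 (adjusted p = 0.00155). The stromal adhesion gene Cdh11 fell (-1.34 ± 0.27, from 3.98 to 2.64; adjusted p = 0.00119), and Col6a2, a chain of collagen VI, fell by 1.23 ± 0.27 (adjusted p = 0.00192). In all, 3675 of 25827 H3K4me3 peaks rose and 4246 fell (30.7%; limma), of which 1430 rose and 1131 fell by more than 2-fold. With the library-code digit as a factor 2332 peaks passed, without the 4 libraries of code digit 6 2459 passed, and with the mouse number series as a factor 3608 passed. With the epithelium minus stroma score of each library as a covariate 162 passed, and among mouse numbers under 100 alone (6 young against 3 aged group 3 libraries) 448 passed.

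The H3K4me3 peaks with the strongest evidence of a gain were each higher in 10 of 10 aged group 3 libraries than every young library. The smallest p was at Card6, a member of the caspase recruitment domain family, on chromosome 15 (5106275 to 5108995, within the gene and 7567 bases from its start). Its mean was 2.77 ± 0.25 in young (SD, n = 7) and 4.06 ± 0.20 in aged group 3 (SD, n = 10), a rise of 1.29 ± 0.11 (adjusted p = 1.68e-08). Dzip1, which encodes a zinc finger protein of the primary cilium, rose by 3.56 ± 0.32 at an internal peak (chromosome 14, 118899379 to 118900295; adjusted p = 4.31e-08). Agmo, whose enzyme cleaves ether lipids, rose by 1.57 ± 0.14 at its promoter (chromosome 12, 37240922 to 37242822). Itgae, the integrin chain of intraepithelial lymphocytes, rose by 2.28 ± 0.23 at an internal peak (chromosome 11, 73111553 to 73112638). The glycosyltransferase gene Gcnt2 rose by 1.00 ± 0.10 and the forkhead transcription factor gene Foxc1 by 1.73 ± 0.20, both at promoter peaks. Further gains were at the cytoskeletal linker gene Dst (2.81), Rusc2 (1.82), Rilpl1 (2.48), Smim31 (2.63), the serine protease gene Tmprss11g (4.14), and Sult1e1 (1.58). Sult1e1 encodes the sulfotransferase that inactivates oestrogen, and the tables gave it a peak 17606 bases upstream of its RefSeq start. Adjusted p for the 12 genes ran up to 3.2e-06.

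Most of the named losses of H3K4me3 lay at promoters. Bahcc1, which encodes a chromatin-binding protein, fell by 1.32 ± 0.15 (chromosome 11, 120232116 to 120238887; from 3.56 ± 0.17 to 2.23 ± 0.47, SD; adjusted p = 1.7e-06). The prolactin receptor gene Prlr fell by 1.37 ± 0.20 (chromosome 15, 10177203 to 10179386; adjusted p = 3.24e-05). The small nucleolar RNA gene Snord104 fell by 1.45 ± 0.20, and a peak downstream of Mos, the oocyte kinase gene, 2308 bases from its start, fell by 0.73 ± 0.096. The somatostatin receptor gene Sstr4 fell by 0.93, Zfp105 by 0.77, Scrn1 by 0.78, the syntrophin gene Sntb1 by 0.56 and the neurotrophic factor receptor gene Gfra2 by 1.10. Away from the RefSeq starts used, the receptor phosphatase gene Ptprs fell by 1.76, the Ras regulator gene Rasa4 by 1.39 and the coronin gene Coro2b by 1.37. The deposited annotation placed the Coro2b peak upstream of the gene, though it lay 121385 bases from the gene's RefSeq start. All 12 were lower than the young mean in 10 of 10 libraries, with adjusted p up to 0.000147. With the epithelium minus stroma score as a covariate, Prlr, Zfp105, Scrn1, Ptprs, Sntb1, Gfra2, Rasa4 and Coro2b no longer passed (adjusted p = 0.075 to 0.154), and among mouse numbers under 100 alone Ptprs, Gfra2 and Rasa4 did not.

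**Figure D1:**
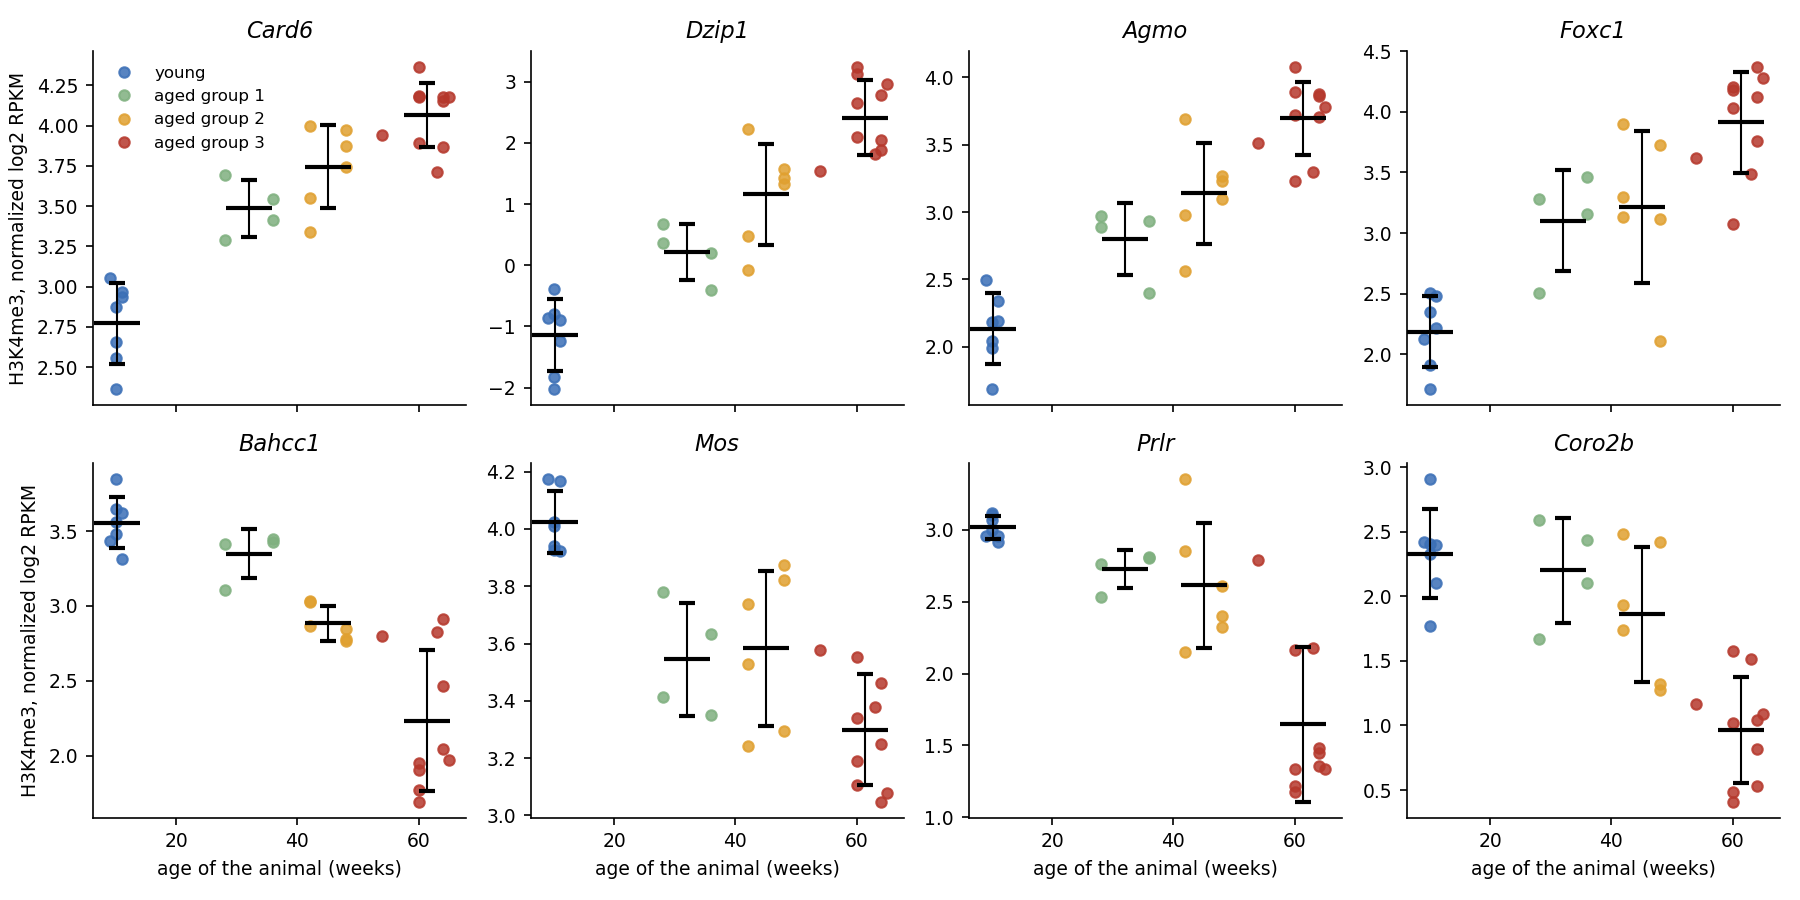
Normalized H3K4me3 (log2 RPKM) against age in weeks for Card6, Dzip1, Agmo, Foxc1, Bahcc1, Mos, Prlr and Coro2b, with a point per library and a black bar for each group's mean ± SD. Card6 went from a mean of 2.77 in young to 4.06 in aged group 3, and Bahcc1 from 3.56 to 2.23.

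Among cell type lists in H3K4me3, the luminal and glandular epithelium rose: 17 of 24 measured genes rose and 0 fell (adjusted p = 1.05e-08; 19 up and 2 down adjusted over the list alone). The transcription factor Ehf (1.25 ± 0.23) and the apical membrane protein gene Prom1 (1.24 ± 0.21) rose with Foxa2 and Ltf. In the endometrial stroma list 14 of 19 genes fell and 1 rose (adjusted p = 0.000162; 1 up and 15 down adjusted over the list alone), among them the homeobox genes Hoxd11 (-1.29 ± 0.28) and Meis2 (-0.63 ± 0.13) and the intermediate filament gene Vim (-1.02 ± 0.23). Smooth muscle genes fell, 8 of 15 with 0 rising (adjusted p = 0.000775; 0 up and 9 down adjusted over the list alone), as at Des (-1.08 ± 0.23), Synpo2 (-0.95), Tpm2 (-0.64) and Myl9 (-0.90), which encode parts of the contractile apparatus. With an estimated correlation these 3 lists did not pass (adjusted p = 0.436 with an estimated correlation for each).

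The difference between the epithelium and stroma scores was higher in aged group 3 than in young by 1.39 for H3K4me3 (exact permutation p = 0.00355) and by 1.09 for H3K27ac (exact permutation p = 0.00607). Within the 5 library-code digits that held both groups (13 libraries) it was higher by 0.92 (exact permutation p = 0.0938) and 0.73 (exact permutation p = 0.146). Within the mouse number series it was higher by 1.46 and 1.28 (exact permutation p = 0.00893 for both). Not all aged group 3 libraries shared the difference: replicates 3, 4 and 10 had H3K4me3 scores of -0.097, -0.066 and -0.90, within the young range of -1.04 to -0.018.

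**Figure D2:**
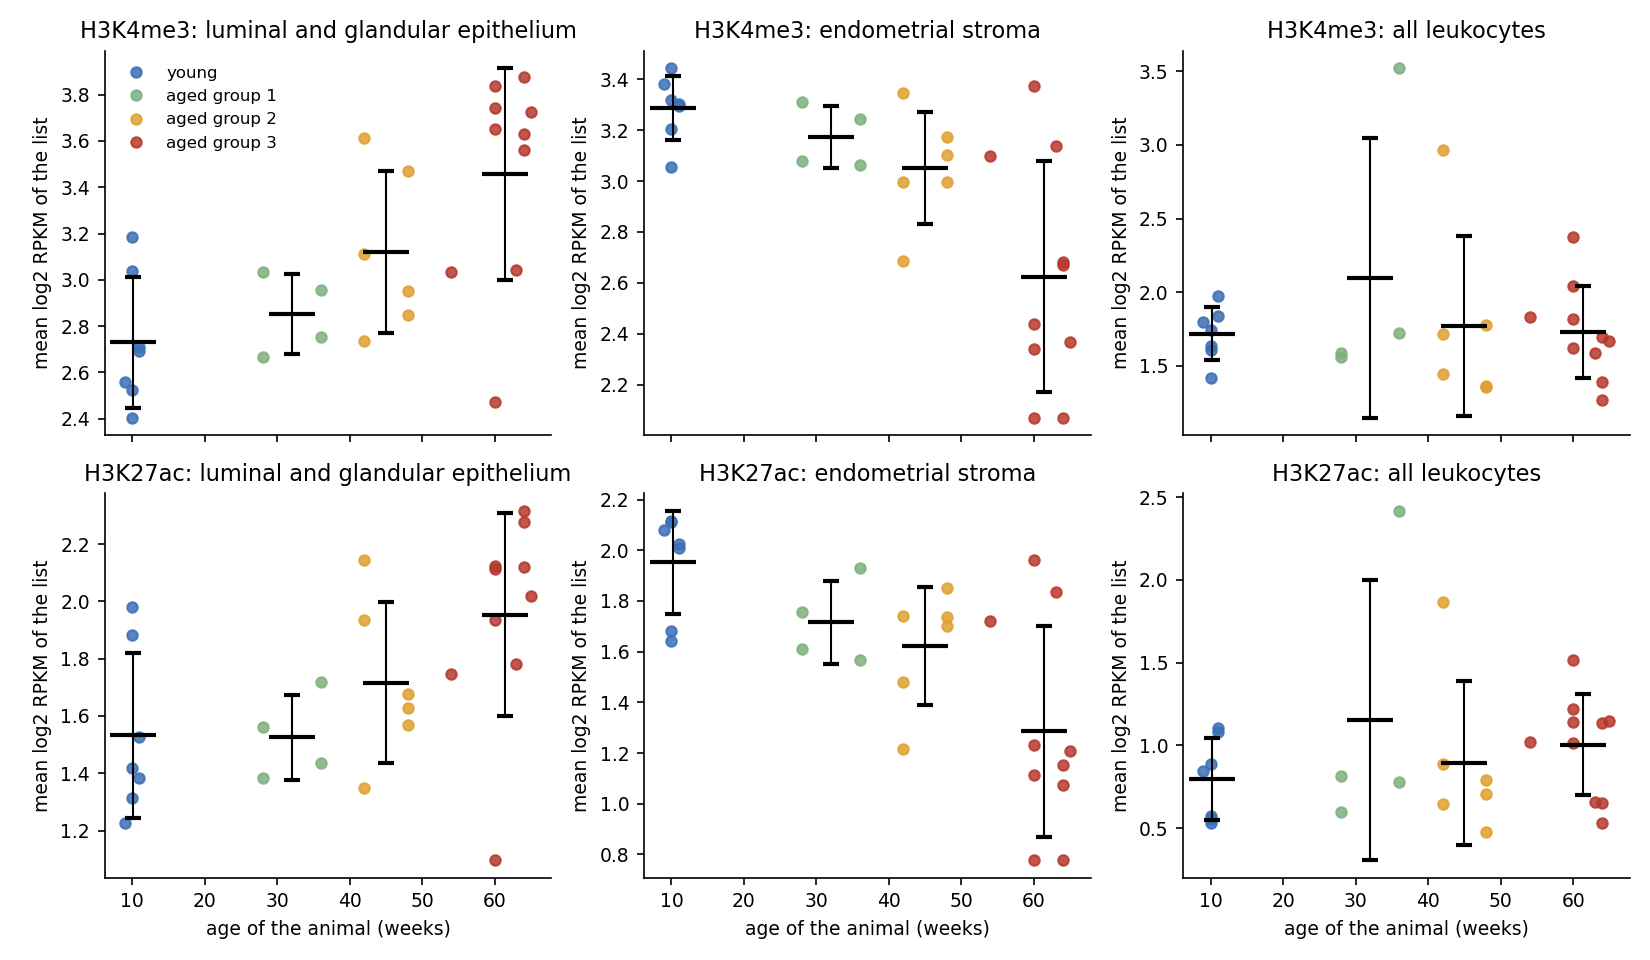
Mean normalized log2 RPKM of the epithelium, stroma and all leukocytes lists in each library against age in weeks, for both marks, with black bars for each group's mean ± SD. The leukocyte scores of aged group 1 replicate 4 (3.52 for H3K4me3) and aged group 2 replicate 5 (2.97) stand above the others of their groups.

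Pathway lists moved beside these cell type lists in H3K4me3. In collagens and matrix 20 of 31 genes fell and 0 rose (adjusted p = 2.42e-05; 1 up and 22 down adjusted over the list alone), including Col4a1 (-1.03 ± 0.22), Spon1 (-1.01) and Loxl1 (-0.94), which crosslinks elastin. In matrix degradation 7 of 13 fell and 0 rose (adjusted p = 0.00433; 0 up and 8 down adjusted over the list alone), with the proteases Adamts1 (-0.60), Adamts5 (-1.08) and Ctsk (-1.18) and the inhibitor Timp2 (-0.84); this call was lost under 1 of 7 other settings (adjusted p = 0.165). In the oestrogen response 9 of 21 rose and 1 fell (adjusted p = 0.000396; the same 9 and 1 adjusted over the list alone), with the water channel Aqp5 (2.70 ± 0.66) and the peptidylarginine deiminases Padi1 (3.26 ± 0.63) and Padi2 (1.58 ± 0.37); 2 of its measured genes, Ltf and Lcn2, are also on the epithelium list, 4 (Ccne1, Mcm2, Mcm3 and Mcm5) on the proliferation list and 1 (Pgr) on the progesterone list. In the interferon response 10 of 26 rose and 0 fell (adjusted p = 2.42e-05; 11 up adjusted over the list alone), with the antiviral enzymes Oas1a (0.63), Oas2 (1.75 ± 0.44) and Oas3 (1.57) and the tether Bst2 (0.22). In the values as deposited Oas1a and Bst2 did not pass (adjusted p = 0.0658 and 0.686). The oestrogen score of aged group 3 replicate 10 (2.11) and the interferon score of replicate 1 (2.93) lay below every young library, and replicate 3 (2.46) for oestrogen and 3, 4 and 10 (3.11, 3.29 and 3.16) for interferon lay within the young range. These 4 lists did not pass with an estimated correlation (adjusted p = 0.436 with an estimated correlation for each).

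The proliferation list passed upward in H3K4me3 with a mean change of 0.25 and 2 of 26 genes past the threshold, Kif11 (0.54 ± 0.16), a mitotic kinesin, and Mcm5 (0.28 ± 0.11), a replicative helicase subunit (adjusted p = 7.05e-05; 0 adjusted over the list alone; adjusted p = 0.554 with an estimated correlation). The proliferation scores of aged group 3 replicates 3, 4, 5 and 10 (3.27, 3.26, 3.41 and 3.42) lay below the young mean of 3.44. In the progesterone response 9 of 20 fell and 1 rose (adjusted p = 0.0411; 1 up and 10 down adjusted over the list alone; adjusted p = 0.554 with an estimated correlation), with the growth factor Bmp2 (-1.11 ± 0.19), Klf15 (-0.88), the hedgehog receptor Ptch1 (-0.29) and Zbtb16 (-1.26). The progesterone call was lost without any of young replicates 4, 5 and 6 or aged group 3 replicates 7, 8, 9 and 10 (adjusted p up to 0.0796) and under 6 of 7 other settings (adjusted p up to 0.434). In the values as deposited the proliferation genes Kif11 and Mcm5 did not pass (adjusted p = 0.111 and 0.515). By fry, which tests a list's direction without comparing it with other genes, 15 H3K4me3 lists passed.

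Other H3K4me3 lists held genes that changed both ways or did not pass as a list. In Wnt signalling 10 of 30 fell and 4 rose (adjusted p = 0.197, with 5 up and 13 down adjusted over the list alone), with Nkd1 (-0.86), Rspo3 (-0.59) and Wnt2 (-0.67) down and Lgr4 (0.39) up. In HOX clusters 4 of 7 fell and 1 rose (adjusted p = 0.1), with Hoxa7 (-1.14), Hoxc5 (-1.21) and Hoxc10 (-1.57) down. In decidualisation and implantation 6 of 20 fell and 3 rose (adjusted p = 0.781, with 6 up and 8 down adjusted over the list alone), with Snai2 (-1.02) and Il11ra1 (-0.70) down and Hbegf (1.02) up. In senescence and cell-cycle arrest 3 of 13 rose and 1 fell (adjusted p = 0.228, with 3 up and 2 down adjusted over the list alone), with the cell-cycle inhibitors Cdkn2a (0.32) and Cdkn2b (0.35) and the cyclin Ccnd1 (0.27) up and Cdkn1c (-0.69) down. In the values as deposited Cdkn2a, Cdkn2b and Ccnd1 did not pass (adjusted p = 0.596, 0.355 and 0.575). In inflammatory and senescence-associated secretion 6 of 23 fell and 3 rose (adjusted p = 0.932), with Hgf (-1.25), Igfbp4 (-0.86) and Igfbp6 (-1.29) down and Nfkbia (0.40) up. In complement 3 of 13 fell and 2 rose (adjusted p = 0.853), with C1s1 (-1.21) and Serping1 (-1.23) down and Cfb (1.91) and Cfi (1.12) up. For HOX clusters, inflammatory secretion and complement the counts adjusted over the list alone were the same.

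Among chromatin regulators 4 of 21 fell and 0 rose in H3K4me3 (adjusted p = 0.55): Tet1 (-0.58), Kmt2a (-0.25), Kdm6b (-0.40) and Ezh2 (-0.15). The immediate early genes had 2 up and 6 down of 20 (adjusted p = 0.139, with 2 and 7 adjusted over the list alone), such as Klf4 (0.51), Atf3 (-0.46), Klf2 (-0.66) and Klf6 (-0.23). The circadian clock list had 0 up and 3 down of 12 (adjusted p = 0.156), at Clock (-0.21), Hlf (-0.49) and Per1 (-0.37). TGF-beta signalling had 2 up and 3 down of 18 (adjusted p = 0.979, with 0 and 1 adjusted over the list alone), with Tgfbr3 (-0.85) lowest of those named. Heat shock and protein folding had 2 up and 2 down of 19 (adjusted p = 0.156, with 2 and 1 adjusted over the list alone), with Hspa5 (0.33) and Calr (0.23) up. Oxidative stress had 2 up and 2 down of 18 (adjusted p = 0.614), with Gsr (0.59) up and Cat (-0.29) down. Antigen presentation (adjusted p = 0.477) and the control genes used in every cell type (adjusted p = 0.21) had 0 of 9 and 0 of 13 past the threshold by limma. Their members with the highest mean were H2-D1 (0.20 ± 0.10), Tapbp (-0.14 ± 0.084), Gusb (0.20 ± 0.099) and Sdha (0.057 ± 0.055). For chromatin regulators, the circadian clock, oxidative stress, antigen presentation and the control genes the counts adjusted over the list alone were the same.

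Of the other cell types in H3K4me3, all leukocytes had 4 up and 0 down of 20 (adjusted p = 0.405). Cytip, a regulator of leukocyte adhesion, rose by 1.67 ± 0.21 (adjusted p = 7e-06), Laptm5 by 1.30, Inpp5d by 1.03 and Ikzf3 by 0.68. Macrophages and monocytes had 2 up of 18 (Cd14, 0.49, and Itgam, 1.31; adjusted p = 0.799). T and NK cells had 1 up and 3 down of 7 (adjusted p = 0.405, with 1 and 4 adjusted over the list alone), with Gata3 (1.19) up and the natural killer receptor gene Ncr1 (-1.76) down. Blood endothelium had 2 up and 2 down of 15 (adjusted p = 0.979), with Sox7 (1.13) and Flt1 (0.78) up and Esam (-0.68) and Kdr (-0.46) down. Lymphatic endothelium had 1 down of 5, Pdpn (-0.48, adjusted p = 0.955). For all of these but T and NK cells the counts adjusted over the list alone were the same. Not tested as lists, for want of measured genes, were pericytes (Kcnj8, -0.84, and Abcc9, -1.0), B and plasma cells (Irf4, -0.61, and Prdm1, -0.26), and adipocytes and mesothelium. Among the last, the mesothelial genes Msln (-1.68 ± 0.41) and Upk3b (-1.57 ± 0.39) fell and the fat cell regulator Pparg (0.33) rose. The test's direction was up where the list's median was negative for complement, TGF-beta signalling, blood endothelium, macrophages and monocytes and all leukocytes, of which the last had a positive mean (0.012). For oxidative stress the median was positive (0.012) and the mean negative (-0.045).

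H3K27ac changed at many of the same genes in aged group 3 against young. Foxc1 rose by 2.60 ± 0.25, from -0.33 ± 0.40 to 2.26 ± 0.44 (SD, n = 7 and n = 10; chromosome 13, 31805367 to 31812683; adjusted p = 4.08e-07), the smallest p of the mark. Smim31 rose by 2.38 ± 0.32, Sult1e1 by 1.01 ± 0.13 and Card6 by 0.95 ± 0.14, and Snord104 fell by 1.18 ± 0.15, Bahcc1 by 1.27 ± 0.17, Mos by 0.94 ± 0.15 and Coro2b by 0.98 ± 0.15. In all, 7812 of 54354 peaks rose and 8092 fell (29.3%; limma), of which 3067 rose and 1459 fell by more than 2-fold. With the library-code digit as a factor 1365 peaks passed, without code digit 6 1891, with the mouse number series as a factor 7334, with the epithelium minus stroma score as a covariate 57, and among mouse numbers under 100 alone 9.

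Further H3K27ac gains named by the rule lay inside or beside Pigyl (1.93), the synaptic scaffold gene Erc2 (1.31), Adck1 (1.21), the actin regulator gene Ppp1r9a (1.92), the fucosyltransferase gene Fut9 (2.35), the G protein subunit gene Gng12 (1.63), Scml4 (1.26) and the phosphatase gene Ppm1l (1.58), with adjusted p up to 0.000219. Further losses were at the ubiquitin ligase gene Hecw2 (-1.46), Ippk (-1.26), which makes inositol hexakisphosphate, the membrane protein gene Emp3 (-0.65), Samd5 (-1.05), the transcription factor gene Nfib (-1.27), the heparan sulfate enzyme gene Extl3 (-0.99), Zfp462 (-1.11) and the sodium pump subunit gene Atp1b2 (-0.95), with adjusted p up to 0.00116. All 24 genes moved the same way in 10 of 10 aged group 3 libraries. With the epithelium minus stroma score as a covariate Fut9, Gng12, Scml4, Card6, Ppm1l, Mos, Ippk, Emp3, Samd5, Nfib, Extl3, Zfp462 and Atp1b2 no longer passed (adjusted p = 0.0541 to 0.328), and among mouse numbers under 100 alone, of the 24, Foxc1 still passed.

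In H3K27ac, 13 of 24 epithelial genes rose and 0 fell (adjusted p = 5.16e-09; adjusted p = 0.539 with an estimated correlation), with Prom1 (1.10 ± 0.19), the transcription factors Pax8 (0.53) and Sox17 (0.60), and Ltf (1.72 ± 0.39). In the oestrogen response 9 of 22 rose and 2 fell (adjusted p = 0.000186, with 9 up and 3 down adjusted over the list alone; adjusted p = 0.539 with an estimated correlation), with Padi1 (1.44), Aqp5 (1.97) and Greb1 (1.07), a cofactor of the oestrogen receptor; 3 measured genes are shared with the epithelium list. In all leukocytes 4 of 17 rose and 1 fell (adjusted p = 0.00609; adjusted p = 0.788 with an estimated correlation), with Laptm5 (1.11), Cytip (1.00) and Lcp1 (0.68) up and Hcls1 (-0.56) down. In macrophages and monocytes 2 of 6 rose, Aif1 (0.89) and Cd14 (0.34; adjusted p = 0.0471; adjusted p = 0.637 with an estimated correlation). For the epithelium, all leukocytes and macrophages the counts adjusted over the list alone were the same. The macrophage call was lost without 10 of the 17 libraries in turn (young replicates 1, 2, 3, 4 and 5 and aged group 3 replicates 2, 6, 8, 9 and 10, adjusted p up to 0.0757) and under 5 of 7 other settings (adjusted p up to 0.43). The all leukocytes call was lost under 4 of 7 (adjusted p up to 0.231).

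Collagens and matrix had 0 up and 19 down of 25 in H3K27ac (adjusted p = 1.5e-05, the same adjusted over the list alone), with Fbn1 (-1.11), Col14a1 (-1.03), Col6a2 (-1.01) and Sparc (-0.91). The endometrial stroma had 1 up and 14 down of 19 (adjusted p = 0.00052, with 1 and 15 adjusted over the list alone), with Hoxd11 (-1.30), Cdh11 (-1.20), Vim (-0.94) and Meis2 (-0.85). Matrix degradation had 0 up and 5 down of 12 (adjusted p = 0.0214, with 0 and 6 adjusted over the list alone), and smooth muscle 0 up and 5 down of 11 (adjusted p = 0.0471, with 0 and 7 adjusted over the list alone), with Ctsk (-1.02) and Des (-0.94) among them. These 4 lists did not pass with an estimated correlation (adjusted p = 0.637 with an estimated correlation for each). The smooth muscle call was lost without young replicate 2, 5, 6 or 7 or aged group 3 replicate 2, 3, 5 or 6 (adjusted p up to 0.108) and under 4 of 7 other settings (adjusted p up to 0.0803). The matrix degradation call was lost under 1 of 7 (adjusted p = 0.0748). By fry 10 H3K27ac lists passed. With the library-code digit as a factor 136 of the 199 named list members of both marks no longer passed, a total that includes members that had not passed before.

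Of the H3K27ac lists that did not pass, Wnt signalling had 2 up and 9 down of 26 (adjusted p = 0.64, with 3 and 10 adjusted over the list alone), with Rspo3 (-0.88), Fzd2 (-0.60) and Wnt5a (-0.49) down and Wnt7b (1.32) up. Inflammatory and senescence-associated secretion had 3 up and 8 down of 23 (adjusted p = 0.971, with 3 and 10 adjusted over the list alone), with Igfbp5 (-0.86) and Igfbp6 (-0.92) down. Decidualisation and implantation had 2 up and 7 down of 19 (adjusted p = 0.908, with 3 and 8 adjusted over the list alone), with Hbegf (0.87) up and Snai2 (-0.94) and Foxo1 (-0.36) down. Progesterone response had 0 up and 4 down of 12 (adjusted p = 0.523, with 0 and 5 adjusted over the list alone), with Ptch1 (-1.30) down. Interferon response had 2 up and 5 down of 25 (adjusted p = 0.64), with Zbp1 (0.64) up and Ifit2 (-0.50) down. Proliferation had 0 up and 1 down of 26, Aurka (-0.44; adjusted p = 0.266). Senescence and cell-cycle arrest had 1 up and 2 down of 11 (adjusted p = 0.607), with Cdkn2b (0.90) up. TGF-beta signalling had 2 up and 4 down of 18 (adjusted p = 0.987, with 2 and 7 adjusted over the list alone), with Tgfbr2 (-0.42) down. Complement had 2 up and 3 down of 12 (adjusted p = 0.786), with C1s1 (-1.0) down. For interferon response, proliferation, senescence and cell-cycle arrest and complement the counts adjusted over the list alone were the same.

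In the same mark, immediate early genes had 1 up and 6 down of 15 (adjusted p = 0.786), with Egr3 (-0.61) among them. Heat shock and protein folding had 0 up and 4 down of 18 (adjusted p = 0.864, with 0 and 3 adjusted over the list alone), with Hspa1a (-0.57) among them. Circadian clock had 1 up, Per2 (0.47), and 2 down of 10 (adjusted p = 0.64). Oxidative stress had 1 up and 3 down of 19 (adjusted p = 0.986, with 0 and 3 adjusted over the list alone). Chromatin regulators had 0 up and 3 down of 22, Ep300 (-0.29), Kdm5c (-0.35) and Kdm6a (-0.24; adjusted p = 0.164). Antigen presentation had 1 up of 6, H2-D1 (0.34, adjusted p = 0.127). Blood endothelium had 2 up and 1 down of 9 (adjusted p = 0.64). The control genes used in every cell type had 0 up and 3 down of 13 (adjusted p = 0.786), with Eef2 (-0.34) and Eef1a1 (-0.24) among them. For all lists of this paragraph but heat shock and oxidative stress the counts adjusted over the list alone were the same. Not tested as lists, for want of measured genes, were HOX clusters (Hoxd11 with Hoxc10, -1.21, and Hoxa7, -0.87), pericytes (Kcnj8, -0.60), lymphatic endothelium (Pdpn, -0.40 ± 0.18, not past the threshold), T and NK cells (Cd5, 0.82, and Thy1, -0.95), B and plasma cells (Cd79b, 0.86, and Prdm1, -0.90), and adipocytes and mesothelium (Pparg, 0.66). The test's direction was up where the median and mean were negative for interferon response, complement, blood endothelium and the control genes, and for senescence and cell-cycle arrest the median (-0.0037) and mean (0.014) differed in sign.

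**Figure D3:**
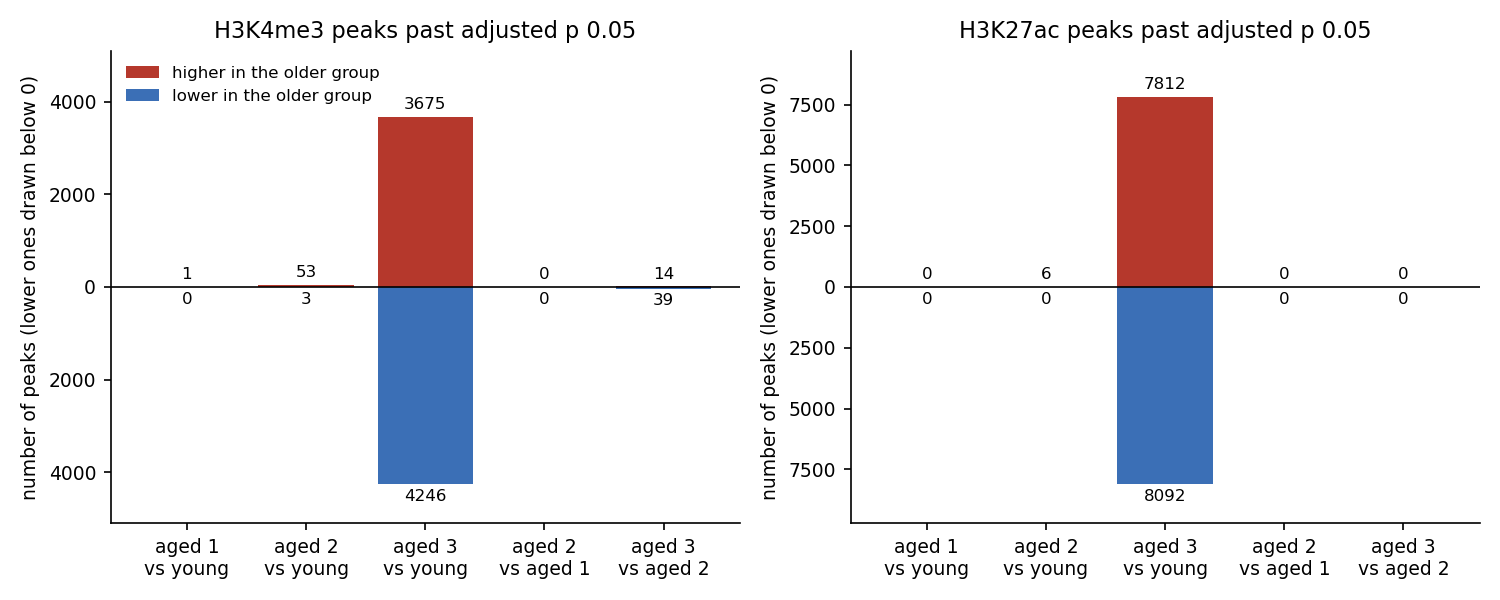
Number of peaks higher (bars above 0) and lower (bars below 0) in each comparison and mark at an adjusted p under 0.05. The bars of aged group 3 against young reach 3675 up and 4246 down for H3K4me3 and 7812 up and 8092 down for H3K27ac, with at most 56 calls in any comparison of neighbouring groups or of the younger aged groups with young.

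Gains and losses differed in where they lay. Promoter peaks made up 27.9% of H3K4me3 gains and 49.5% of losses, against 45.5% of all tested peaks. For H3K27ac they made up 8.91% of gains and 26% of losses, against 20.1% of all peaks. Among called peaks at promoters, gains made up 32.8% for H3K4me3 and 24.8% for H3K27ac; away from promoters they made up 55.3% and 54.3%. Of H3K4me3 gains 1.14% lay on chromosome X, where 2.76% of tested peaks lay. The sets also differed in signal: the median log2 RPKM was 1.99 for H3K4me3 gains, 2.49 for losses and 2.7 for all tested peaks. For H3K27ac it was 1.05, 1.29 and 1.21. Peaks are not independent, these shares were not tested, and location was not separated from signal level.

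Both marks moved together at shared positions. Of H3K4me3 peaks, 20883 (80.9%) overlapped an H3K27ac peak, and the fold changes of the 2 marks correlated across them (Pearson r = 0.784, Spearman rho = 0.739; peaks are not independent replicates). When animals were permuted between the groups together in both marks, 2 of 100 draws, the real one included, gave an r as high, with a highest other r of 0.79 and a median of 0.437. Both marks passed at 3321 of them, 1505 up in both and 1785 down in both, against 336.7 and 553.9 expected for independent calls, and 31 in opposite directions, such as those at Ap4e1 and Pknox2. Each of the 27 animals had an H3K4me3 profile, relative to its group, that matched its own H3K27ac profile best (mean r = 0.387, against -0.0543 for other animals of the group).

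**Figure D4:**
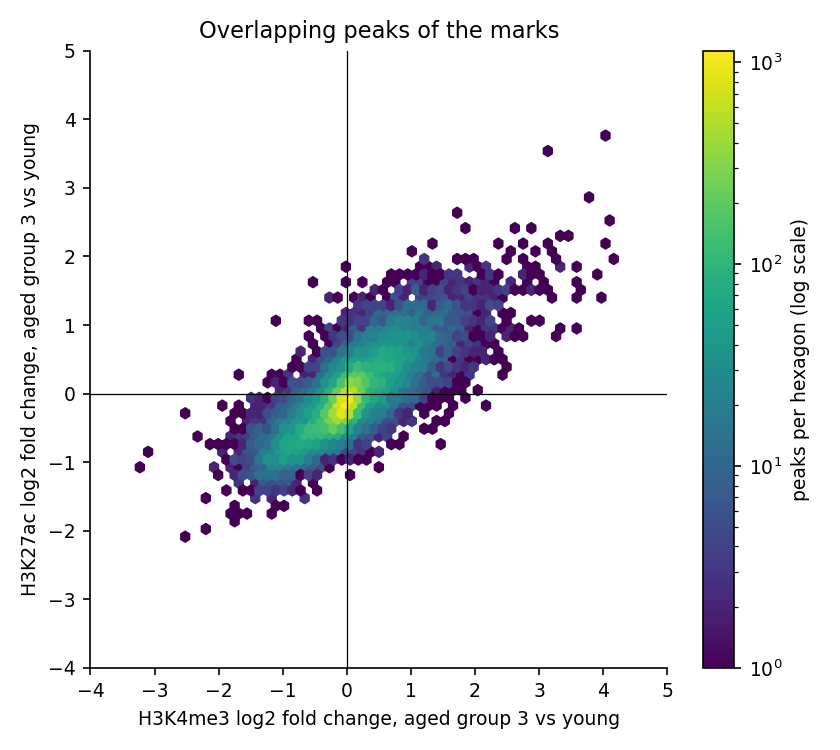
Log2 fold change of H3K27ac against that of H3K4me3, aged group 3 against young, at 20883 overlapping peaks. Lighter hexagons hold more peaks. The peaks run along the diagonal (Pearson r = 0.784).

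Aged group 2 against young asks whether marks have changed by 42 to 48 weeks. H3K4me3 rose at Card6 (0.97 ± 0.12; adjusted p = 8.42e-05), Gcnt2 (0.78 ± 0.12), Agmo (1.01 ± 0.16) and Cytip (1.51 ± 0.24), higher than every young library in 6 of 6 libraries, or 5 of 6 for Gcnt2. It fell at Cir1, a transcriptional corepressor gene (-0.23 ± 0.042), and at Gnasas1, the antisense transcript of the imprinted Gnas locus (-0.79 ± 0.17). H3K27ac rose at Foxc1 (1.82 ± 0.28), Sult1e1 (0.91 ± 0.15) and Ceacam12 (3.10 ± 0.57; 1 young library had 0 reads there). Of 56 H3K4me3 peaks 53 rose and 3 fell, and 53 of those gains were also gains in aged group 3 (7.54 expected for independent calls). Both groups share the young libraries. With the young libraries split between the comparisons a median of 3 peaks rose in aged group 2, of which a median of 2.5 were shared. All 6 H3K27ac calls were gains. The other 3, chosen after their values were seen, were at Gm2619 (2.61 ± 0.41), Gm5155 (3.42 ± 0.59) and 9530026P05Rik (1.68 ± 0.30). All 6 animals of aged group 2 and 4 of aged group 1 had mouse numbers over 200, against 1 of 7 young, so these comparisons are nearly confounded with the mouse number series. With that series as a factor 4 H3K4me3 and 0 H3K27ac peaks passed, Agmo, Cytip, Cir1, Gnasas1, Foxc1, Sult1e1 and Ceacam12 not among them, and by voom 27 and 0 passed. The H3K4me3 count fell to 27 to 33 without any of young replicates 1, 2 and 3 or aged group 2 replicates 1, 3, 4, 5 and 6. The H3K27ac count was 0 without aged group 2 replicate 5, 10 without its replicate 3, and 3 without its replicate 4 or 6 or young replicate 1, 3 or 7.

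Aged group 1 against young asks whether changes are already present at 28 to 36 weeks. Among genes the naming rule allowed, the H3K4me3 peaks with the smallest p were higher at Card6 (0.71 ± 0.14; adjusted p = 0.111), Gcnt2 (0.67 ± 0.13; adjusted p = 0.111) and Pik3cg, the leukocyte phosphoinositide kinase gene (1.09 ± 0.23; adjusted p = 0.204), and lower at Mos (-0.48 ± 0.12), the potassium channel gene Kcnc1 (-1.09 ± 0.30) and Igdcc3 (-0.89 ± 0.25), and did not pass. Card6, Pik3cg, Mos and Kcnc1 lay beyond all young libraries in 4 of 4 libraries, and Gcnt2 and Igdcc3 in 3 of 4. A single H3K4me3 peak passed, at Gm45734 (chromosome 8, 72032075 to 72033077), higher by 1.66 ± 0.28 (adjusted p = 0.0463), named here after its value was seen. In H3K27ac the smallest p among such genes were at Foxc1 (1.51 ± 0.32), Morrbid, a long noncoding RNA gene of short-lived leukocytes (1.52 ± 0.35), Sult1e1 (0.70 ± 0.16), Hecw2 (-1.39 ± 0.29), the endothelial transcription factor gene Erg (-0.97 ± 0.24) and Zbtb8a (-1.01 ± 0.25; adjusted p = 1 for each). By limma 1 H3K4me3 and 0 H3K27ac peaks passed, with 932 and 2134 at an unadjusted p under 0.05 (1291.4 and 2717.7 expected by chance), and by voom 3 and 0. The single H3K4me3 call was lost (a count of 0) without young replicate 2, 3, 5 or 6 or any of aged group 1 replicates 1, 2, 3 and 4, and the count was 2 without young replicate 4.

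Aged group 2 against aged group 1 gave 0 calls in both marks by limma and by voom, with 659 and 1511 peaks at an unadjusted p under 0.05. Among genes the naming rule allowed, the smallest p in H3K4me3 were at Snorc (1.2 ± 0.31), the arginine transporter gene Slc7a1 (1.55 ± 0.43), the smooth muscle gene Lmod1 (1.14 ± 0.32), Cir1 (-0.20 ± 0.049), Parp6 (-0.22 ± 0.060) and Cilp2 (-2.0 ± 0.58). In H3K27ac they were at Ablim1 (0.93 ± 0.22), Pank2 (1.25 ± 0.30), the clock gene Npas2 at separate peaks (1.33 ± 0.34 and -1.20 ± 0.32), Prune2 (-0.85 ± 0.22) and Dpp8 (-1.73 ± 0.47). None passed (adjusted p = 1 for each). Without aged group 1 replicate 1 or aged group 2 replicate 1 the H3K4me3 count was 1.

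Aged group 3 against aged group 2 asks what differs between the oldest groups. H3K4me3 rose at Unc79 (1.71 ± 0.33), the monocarboxylate transporter gene Slc5a8 (1.07 ± 0.22), the myosin gene Myo1e (0.26 ± 0.054) and Cir1 (0.19 ± 0.039). It fell at Ptgis, the prostacyclin synthase gene (-1.17 ± 0.21), Scrn1 (-0.70 ± 0.13), the calcium channel subunit gene Cacnb2 (-1.11 ± 0.21) and Sec24d (-1.23 ± 0.24). Adjusted p was 0.0405 for each, the smallest of the comparison, and 14 peaks rose and 39 fell by limma (439 calls by voom). No call was left with the library-code digit as a factor (0 peaks; adjusted p = 0.0751 to 0.0768 for the 8 genes). The count was 0 without any of aged group 2 replicates 1, 2, 3 and 4 or aged group 3 replicates 2, 5, 6, 7, 8 and 9, and 4 without aged group 2 replicate 6. It was 87, 1198, 1241 and 2079 without aged group 3 replicates 1, 3, 4 and 10, and 995 without aged group 2 replicate 5. In H3K27ac 0 peaks passed by limma and by voom, with 8718 at an unadjusted p under 0.05, and 34 and 4 passed without aged group 2 replicate 5 and aged group 3 replicate 3. The smallest p there among genes the rule allowed were at Spata16 (1.63 ± 0.34), Vps13b (0.97 ± 0.22), Pof1b (1.23 ± 0.28), Herpud2 (-0.43 ± 0.081), Galnt2l (-0.61 ± 0.12) and Saysd1 (-0.35 ± 0.071; adjusted p = 0.22 for each).

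Across all 27 libraries, the genes named for the trend with age in weeks were all among those named for aged group 3 against young. Their order was only partly the same. For each 10 weeks H3K4me3 rose at Card6 by 0.25 ± 0.021, at Dzip1 by 0.69 ± 0.060, at Agmo by 0.30 ± 0.027 and at Itgae by 0.43 ± 0.042, and fell at Bahcc1 by 0.26 ± 0.031, at Mos by 0.13 ± 0.018, at Snord104 by 0.28 ± 0.040 and at Sstr4 by 0.18 ± 0.027 (adjusted p up to 3.26e-05). H3K27ac rose at Foxc1 (0.49), Pigyl (0.37), Smim31 (0.46) and Ppp1r9a (0.37) and fell at Snord104 (-0.23), Bahcc1 (-0.25), Mos (-0.18) and Samd5 (-0.22; adjusted p up to 2e-04). In all, 3911 H3K4me3 peaks rose and 4487 fell with age, and 8549 H3K27ac peaks rose and 8954 fell. Without the young libraries 3132 and 426 peaks passed, with the library-code digit as a factor 2842 and 2929, and with the epithelium minus stroma score as a covariate 152 and 55. Without the young libraries Mos did not pass in H3K4me3 (adjusted p = 0.0868), nor Foxc1, Smim31, Bahcc1, Mos and Samd5 in H3K27ac (adjusted p = 0.0523 to 0.0904).

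Fold changes of aged groups 2 and 3 against young correlated across peaks at r = 0.785 for H3K4me3 and 0.801 for H3K27ac, which includes the error of the shared young libraries. In simulation, unchanged groups shared a simulated young group, all drawn with replacement from the group-centred libraries of all ages. Their spread was thus that of all groups, not of the young libraries alone. They gave a mean r of 0.528 and 0.523 and a highest r of 0.945 and 0.959. The covariance was 0.153 and 0.165, against means of 0.0328 and 0.0415 in simulation, with 1 and 2 of 100 simulations as high. With the young libraries split between the comparisons r was 0.601 and 0.579. For aged groups 1 and 3 r was 0.476 and 0.509, against means of 0.479 and 0.464 in simulation (highest 0.909 and 0.9) and 0.305 and 0.297 with split young libraries. Their covariance was 0.0796 and 0.0901 (0.0349 and 0.0439 in simulation), with 6 and 16 of 100 simulations as high. For aged groups 1 and 2 r was 0.613 and 0.596, against means of 0.39 and 0.383 (highest 0.846 and 0.864), and 0.308 and 0.26 with split young libraries. The covariance of that pair was 0.0548 and 0.0625 (0.0288 and 0.0353 in simulation), with 15 and 14 of 100 simulations as high, so it was not separated from no change. Peaks are not independent replicates, and 6 such pairs were compared.

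The median deposited log2 RPKM over peaks did not differ detectably with age in either mark. Being scaled to each library's total reads, this value cannot show a global gain or loss of a mark. The median deposited log2 RPKM of H3K4me3 was 2.91 ± 0.28 in young, 2.63 ± 0.23 in aged group 1, 2.85 ± 0.29 in aged group 2 and 2.78 ± 0.25 in aged group 3 (SD; differences from young -0.28, -0.067 and -0.13; exact permutation p = 0.139, 0.581 and 0.339). Quantile normalization removed these differences, so the changes at single peaks are relative to them. For H3K27ac it was 1.37 ± 0.16, 1.47 ± 0.13, 1.33 ± 0.055 and 1.27 ± 0.18 (exact permutation p = 0.327, 0.597 and 0.273), and the adjusted p of the 6 tests were 0.509 to 0.597. Without young replicate 5 the H3K4me3 difference was -0.38 in aged group 1 (exact permutation p = 0.019) and -0.23 in aged group 3 (permutation p = 0.0282), and without aged group 1 replicate 2 it was -0.39 in aged group 1 (exact permutation p = 0.0417).

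Libraries of aged group 3 differed from each other in H3K4me3 by a mean of 0.71, against 0.538 in young, 0.583 in aged group 1 and 0.656 in aged group 2 (aged group 3 minus young 0.173; exact permutation p = 0.0295, adjusted p = 0.059 over both marks). For H3K27ac the values were 0.766, 0.622, 0.678 and 0.737 (difference 0.144; exact permutation p = 0.147, adjusted p = 0.147). In the values as deposited the differences were 0.172 (exact permutation p = 0.227) and 0.267 (exact permutation p = 0.0117), and with centred libraries 0.18 and 0.254 (exact permutation p = 0.0216 and 0.00684). Without any of young replicates 1, 2, 3, 6 and 7 or aged group 3 replicates 3, 4 and 10 the H3K4me3 difference no longer passed before adjustment (0.13 to 0.167; exact permutation p = 0.0661 to 0.0916), and without aged group 3 replicate 9 the H3K27ac difference passed (0.164; exact permutation p = 0.0473).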

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

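The tests of the stromal share, of single libraries, of blood and of other splits of the samples, and the comparison of lists between the marks, were chosen only after the result each concerns was seen; those of the library-code digit and the mouse number series were chosen before.

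The higher marks at epithelial genes and lower marks at stromal genes in aged group 3 were weighed first. A batch that follows the mouse number series is argued against, since the epithelium minus stroma score was higher by 1.46 for H3K4me3 and 1.28 for H3K27ac within the series (exact permutation p = 0.00893 for both). That rests on few libraries: numbers over 200 held 1 young and 7 aged group 3 animals, and numbers under 100 held 6 and 3. A lower share of stromal cells and nothing else would raise epithelial and smooth muscle genes alike if stromal cells lack marks at the latter. Whether they do was not tested. Epithelial genes changed by 1.32 and 0.94 more than smooth muscle genes (exact permutation p = 0.00134 and 0.00463), which fell themselves (-0.60 and -0.52, exact permutation p = 0.00175 and 0.00159). These values argue against a lower stromal share alone only under that condition. A batch that follows the library-code digit cannot be told apart from age, because only 13 libraries lie in the 5 digits that hold both groups, and there the difference was 0.92 and 0.73 (96 arrangements, exact permutation p = 0.0938 and 0.146). A higher share of epithelium in the tissue pieces and age itself stay open, neither of them tested, and other causes were not weighed.

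The score of the all leukocytes list stood apart from the others of the group in aged group 1 replicate 4 (3.52 for H3K4me3, others 1.56 to 1.72, and 2.42 for H3K27ac, others 0.60 to 0.82) and aged group 2 replicate 5 (2.97, others 1.35 to 1.77, and 1.87, others 0.47 to 0.89). A fault of a single immunoprecipitation is argued against, since the same animals stood apart in the other mark, by gaps of 0.88 and 0.705 of the group's range in H3K27ac. Blood left in the tissue cannot be told apart, since few lymphocyte genes were measured: for H3K4me3 the score of T and NK cells (7 genes) differed from the mean of the others by 0.013 and -0.68 and that of B and plasma cells (3 genes) by 0.27 and 0.025. The macrophage and monocyte score was higher by 1.95 and 1.2 in the same libraries. No biological explanation was tested, since the labels set these animals apart in no way.

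H3K4me3 rose more than H3K27ac at the same genes, aged group 3 against young, for the oestrogen response (0.48; 20 genes), interferon response (0.40; 25 genes), proliferation (0.23; 26 genes) and luminal and glandular epithelium (0.36; 22 genes), each with an adjusted exact permutation p of 0.0225 over 25 lists. For complement the difference was 0.27 (9 genes; adjusted exact permutation p = 0.0319). Most other lists also differed upward without passing, such as the control genes used in every cell type (0.13), heat shock and protein folding (0.15) and chromatin regulators (0.11; adjusted exact permutation p = 0.157, 0.116 and 0.197); no general offset between the marks was taken off these differences. The stroma and collagen lists differed by 0.0068 and -0.0025 (adjusted exact permutation p = 0.96 and 0.972).

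Some libraries lay far from the others of their group. The median deposited H3K4me3 was low in young replicate 5 (2.32), aged group 2 replicate 1 (2.27) and aged group 3 replicate 6 (2.15). The same libraries had low shares of reads in peaks, 39.7%, 39.7% and 36.3%. Aged group 1 replicate 3 had 48.3 M H3K4me3 reads, against at most 11.45 M in its group, and a low interferon score (2.94). In H3K27ac the matrix degradation score was low in young replicate 4 (1.39) and the epithelial score was low in aged group 3 replicate 10 (1.10).

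Single genes also stood apart. H3K4me3 was low at Agmo (2.40) and Gfra2 (1.61) in aged group 1 replicate 4, at Itgae in aged group 3 replicate 10 (2.37), at Rusc2 in young replicate 1 (-0.15) and at Bahcc1 in aged group 1 replicate 2 (3.11). H3K27ac was low at Foxc1 (0.24) and Bahcc1 (1.44) in aged group 1 replicate 2, and high at Bahcc1 in aged group 2 replicate 3 (1.83) and at Nfib in aged group 3 replicate 4 (1.88). Chance sets apart about 1 in 20 groups. Of 288 groups 23 held such a library, against 14.4 expected, with 7 of 24 for library values (1.2 expected), 7 of 72 for list scores (3.6 expected) and 9 of 192 for named genes (9.6 expected).

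Other splits of the same libraries, 100 per result with the real one included, tested whether chance could give as many calls. By this count, not adjusted over the results tested, chance is argued against for aged group 3 against young. There 2 splits of H3K4me3 and 2 of H3K27ac gave as many calls as the real 7921 and 15904. Another split gave more calls in each mark (9250 and 17574), so chance is not excluded. It is also argued against for the age trend (1 and 1 splits, real 8398 and 17503, highest other 1340 and 1). For aged group 2 against young 1 and 2 splits gave as many (real 56 and 6, highest other 2 and 25). This argues against chance in the same way, though not against the mouse number series, which nearly follows those groups. For the single H3K4me3 call of aged group 1, 2 splits gave as many (highest other 1). That call was lost without any 1 of its 4 aged libraries. Fewer peaks than expected had an unadjusted p under 0.05 (932 against 1291.4), so chance stays open there. Chance also stays open for the number of lists (16 and 6 splits, real 9 and 8, highest other 14 and 9). Other splits called a median of 5 H3K4me3 and 4 H3K27ac lists, and only 8 and 12 splits called none. A list call at the preset correlation was thus common under other groupings of the same libraries. Chance stays open as well for the 53 H3K4me3 calls of aged group 3 against aged group 2 (8 splits, highest other 7640). Results of 0 calls were met by all 100 splits (H3K27ac of aged group 1 against young, highest other 2, and of aged group 3 against aged group 2, highest other 19644, and aged group 2 against aged group 1, highest other 1 and 3). Splits with that many calls point to a structure of the samples: in the highest ones the epithelium minus stroma score differed between the groups by -1.42 and -1.0 for aged group 3 against young (real 1.39 and 1.09) and by -1.27 and -1.04 for aged group 3 against aged group 2 (real 0.76 and 0.57).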

How the results depend on the processing

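Chosen only after the result was seen were voom, the epithelium minus stroma score or reads in peaks as a covariate, leaving out code digit 6, fitting only the groups compared, the trend without young libraries, mouse numbers under 100 for the library level, and any RefSeq gene start; the other settings were chosen before. Counts below are of peaks past the threshold, and where no reason is given the cause was not tested. No count of aged group 2 against aged group 1 changed under any setting but leaving out a library, and the correlation of the marks stayed between 0.75 and 0.799. Of the genes named for a comparison or the age trend none reversed under the settings run, though with the score as a covariate 33 of 111 named values no longer passed. With the library-code digit as a factor 11 of 111 named values and 136 of 199 list members no longer passed, and with the mouse number series 7 and 83. Both totals include values that did not pass in the main fit and so could not be lost. Same-numbered libraries did not all correlate in any comparison, with 1 and 2 of 7 pairs over 0.1 for aged group 3 and young (mean -0.0319 and -0.0203). The most were 4 of 6 in H3K27ac for aged group 2 and young (mean 0.205), where the replicate block gave 9 peaks against 6. With the replicate block 6842 H3K4me3 and 16064 H3K27ac peaks passed for aged group 3 against young. H3K27ac had a median of 50 reads per peak against 120, and 48% of simulated changes of 1 on the log2 scale were recovered against 69%; what part of this depth accounts for was not tested.

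For aged group 3 against young (7921 H3K4me3 and 15904 H3K27ac peaks) the counts were 2332 and 1365 with the library-code digit as a factor, 3608 and 7334 with the mouse number series as a factor, 2459 and 1891 without libraries of code digit 6, 162 and 57 with the epithelium minus stroma score as a covariate, and 14396 and 34559 with array weights. Fewer peaks tested gave 5247 and 10547 (lowest 25% by mean left out), a threshold of 0.01 gave 3531 and 4313, and fewer libraries gave 448 and 9 (mouse numbers under 100). In that last setting Pdpn of the H3K4me3 lists reversed, to 0.047 (adjusted p = 0.908; -0.48 in the full comparison). For the age trend (8398 and 17503) the counts were 2842 and 2929 with the digit, 2815 and 4043 without digit 6, 152 and 55 with the score, and 3132 and 426 without the young libraries.

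For aged group 2 against young (56 H3K4me3 and 6 H3K27ac peaks) the H3K4me3 count was 98 with libraries centred on their median, 32 with log2(RPKM + 1), 30 with the lowest peaks left out, 31 with the digit, 4 with the mouse number series, 27 by voom, 12 without digit 6 and 24 with only the groups compared. The H3K27ac count was 0 with log2(RPKM + 1), 2 with the lowest peaks left out, 2 without the mean-variance trend, 1 with the digit, 0 with the mouse number series, 0 by voom and 1 without digit 6. For aged group 1 against young (1 and 0) the H3K4me3 count was 0 for the values as deposited, with log2(RPKM + 1), with the lowest peaks left out, with the mouse number series, with the replicate block, with reads in peaks as a covariate, without digit 6 and with only the groups compared, 4 with the digit and 3 by voom. The H3K27ac count was 1 with the score as a covariate.

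For aged group 3 against aged group 2 (53 and 0) the H3K4me3 count was 0 for the values as deposited, with the digit, with the score, with reads in peaks as a covariate, without digit 6 and with only the groups compared. It was 87 with log2(RPKM + 1), 28 with the lowest peaks left out, 185 with the mouse number series, 2 with the replicate block, 439 by voom, and 71 with libraries centred on their median, of which 12.7% were gains against 26.4% of the 53. The H3K27ac count was 1 with reads in peaks as a covariate.

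With an estimated correlation 0 lists passed in H3K4me3 and 0 in H3K27ac (9 and 8 with the preset one), and with the mean of all peaks of a gene 5 passed in H3K27ac. The spread of H3K4me3 differed by 0.172 for the values as deposited (exact permutation p = 0.227), and that of H3K27ac by 0.267 (exact permutation p = 0.0117) for the values as deposited and 0.254 with centred libraries (exact permutation p = 0.00684).

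Leaving out each library in turn gave, for H3K4me3 and H3K27ac, 0 to 2 and 0 to 0 peaks for aged group 1 against young, 27 to 55 and 0 to 10 for aged group 2, 6145 to 9763 and 10890 to 21274 for aged group 3, 0 to 1 and 0 to 0 for aged group 2 against aged group 1, 0 to 2079 and 0 to 34 for aged group 3 against aged group 2, 6349 to 9735 and 12543 to 21471 for the trend, and 8 to 9 and 6 to 8 lists. The differences in library level ran from -0.39 to -0.21 and 0.043 to 0.14 for aged group 1, -0.17 to 0.047 and -0.086 to 0.0021 for aged group 2, and -0.23 to -0.061 and -0.14 to -0.056 for aged group 3. That of aged group 2 reversed without its replicate 1 (H3K4me3, 0.047) and without young replicate 4 (H3K27ac, 0.0021). The spread difference ran from 0.13 to 0.216 and 0.0939 to 0.186.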

Other observations

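All tests of explanations in this part were chosen only after the result was seen.

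The scores of the epithelium and stroma lists are given here for all groups, without a test. The epithelium minus stroma score of H3K4me3 was -0.56 ± 0.40 in young (SD, n = 7), -0.32 ± 0.063 in aged group 1 (SD, n = 4), 0.071 ± 0.53 in aged group 2 (SD, n = 6) and 0.83 ± 0.90 in aged group 3 (SD, n = 10). For H3K27ac it was -0.42 ± 0.49, -0.19 ± 0.042, 0.095 ± 0.50 and 0.67 ± 0.74. The oestrogen response score of H3K4me3 went from 2.28 ± 0.13 in young to 2.36 ± 0.20, 2.69 ± 0.49 and 3.07 ± 0.58, and its SD was larger in the older groups. The interferon score was 3.10 ± 0.12 in young and 3.49 ± 0.38 in aged group 3 for H3K4me3, and 2.01 ± 0.096 and 2.00 ± 0.18 for H3K27ac.

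A hypothesis was tested that the gains of aged group 3 against young may reflect something other than the mix of epithelium and stroma, and the mix cannot be told apart. With the epithelium minus stroma score as a covariate 109 of 3675 H3K4me3 gains (median change 0.86 before and 0.24 after) and 33 of 7812 H3K27ac gains (0.90 before and 0.31 after) still passed. Something that sets only the young libraries apart cannot be told apart either. Among the 20 older libraries 1406 and 281 of the gains passed as age trends. The median slope of all gains, on the scale of the age trend above, was 0.23 and 0.25 there. With the young libraries included it was 0.17 and 0.18, and 99% of the gains kept their direction in both marks. The slope was thus not smaller without the young libraries, but the choice of peaks high in aged group 3 favours such a slope. Nor can a batch that follows the mouse number series be told apart. With the series as a factor the median change was 0.83 and 0.91 (0.86 and 0.90 before), with 100% in the same direction. Of the gains 1808 and 3556 passed (49.2% and 45.5%). The gains were chosen in the same comparison, which favours a kept size and direction, so the series stays open. Of the 12 named gains per mark, picked for their small p and so no test of these, 12 and 7 passed with the score, 11 and 5 without the young libraries, and 12 and 12 with the series.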
